A study of Mus musculus with 14 samples.

How the data were processed

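RNA from the anterior cortex of 14 C57BL/6J mice aged 15 months was sequenced, 1 library per mouse. There were 4 wild-type mice (WT), 6 mice heterozygous for the DG allele of Vcp (DG/+) and 4 homozygous mice (DG/DG). Per the labels, RNA was extracted with an RNeasy kit and libraries followed standard Illumina protocols. Each library carries its own mouse number, so replicates are separate mice. In WT the mouse number and the replicate number differ for 3 of the 4 mice, and replicates are named here by replicate number. The labels give no sex, litter, batch or sequencing date.

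The authors deposited 1 table with 24939 RefSeq transcripts. It holds raw read counts of the 14 libraries, and a first set of columns that the authors normalized, in log2 units, with an upper quartile of 9.36 in every library. How these log2 values were made is not stated. The deposited table also holds the authors' edgeR average level and log2 fold change of DG/+ and DG/DG against WT, and the authors' p-value and false discovery rate for each. The submitters' processing notes name genome build mm10 and edgeR without a version, and the aligner and the counting tool are not given in the sources used here. All columns were used. The tests below started from the raw counts.

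Several transcripts of a gene can hold the same reads. For each of the 19360 gene symbols the transcript with the most reads was therefore kept, which left out 5579 further transcripts of 3557 genes. Of these, 1030 had counts identical to another transcript of the gene. Coordinates came from a RefSeq table of the GRCm38.p6 assembly (mm10), to which 24490 transcripts were matched by accession. Transcript lengths and GC contents were computed from GENCODE transcript sequences linked by RefSeq accession, and were available for 18416 gene symbols. The 15 mitochondrially encoded genes were not in the deposited table, so that list was not tested.

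Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed by edgeR's default filter, which left 14565 genes, and libraries were scaled by TMM. The quasi-likelihood model with robust settings was fitted to all 14 libraries, and the 3 pairs of genotypes were contrasted. A further fit used the number of DG alleles as a number. Genes counted as changed when the Benjamini-Hochberg adjusted p was below 0.05. Levels are CPM (counts per mega-count of the library) with TMM scaling, given as mean ± SD. Vcp was also tested on log2 CPM by a two-sided exact permutation test, adjusted over the 3 comparisons.

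Gene lists (32) were written from general knowledge of the cell types and pathways of the brain. The 31 lists with at least 5 tested genes were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2. Adjustment was over the 31 lists. Members past 0.05 were counted after adjustment over all genes and adjusted over the list alone. The set test was repeated with an estimated correlation, with fry, and as an exact permutation test of the list's mean per library.

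Named genes follow a rule. For each comparison it takes Vcp, the 10 genes with the smallest p in each direction among genes with a mean of at least 1 CPM, and up to 4 members with the smallest p from each list that the text names. Genes that did not pass the adjusted threshold are given as values, not as changes. Any other gene named was chosen after its values were seen.

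The groups, tests, gene lists and naming rule were chosen before the data were examined, as were these alternatives: DESeq2 1.42.0, limma-voom with and without sample quality weights, other size factors, other filters on low counts, only the 2 genotypes compared, the replicate number as a block, the Xist level as a covariate, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, and leaving out each library in turn. Chosen after the data were seen were tests of every transcript, edgeR's exact test on every transcript, limma-trend on the authors' log2 values, a fit without 4 libraries with many transcripts of pituitary, choroid plexus or cerebellum (DG/DG replicate 1, WT replicates 2 and 3, DG/+ replicate 2; DG/+ replicates 1, 5 and 6 stayed in with Ttr at 525, 536 and 192 CPM), an offset for transcript length and GC content fitted by lowess in each library, a comparison with the 100 genes (mean of at least 1 CPM) nearest in length, or in length and GC content, the permutation test of list means, and marker lists for pituitary, hypothalamus, cerebellum and basal forebrain.

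Total counts per library were 8.65 to 15.91 M (M for mega) over the kept transcripts. The precision is given as the 95% confidence interval of each fold change. In counts simulated without genotype differences, genes changed by 2-fold were recovered in 73.1% of cases for DG/DG against WT, 88.1% for DG/+ against WT and 82.1% for DG/DG against DG/+. At 1.5-fold these shares were 41.8%, 59.7% and 49.3%. Each share rests on 67 genes in a single draw of counts, picked among genes with a mean of at least 1 CPM. The shares therefore do not cover tested genes with lower levels. In the same simulations 7, 12 and 3 unchanged genes were called. A list raised 1.2-fold in simulated counts was called with an adjusted p of 2.61e-21, and 0 other lists were called. These counts were drawn for each gene independently, while the raised list, the proteasome subunits, had an estimated correlation of 0.306 in the real libraries. The simulation therefore does not show how often camera calls unchanged lists in real libraries.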

Results

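Vcp encodes an ATPase that extracts proteins from complexes and aggregates, and the series title concerns a dominant hypomorphic mutation of it and the disaggregation of tau filaments. Transcript levels were measured in the anterior cortex of mice aged 15 months with 0 (WT, n = 4), 1 (DG/+, n = 6) or 2 (DG/DG, n = 4) copies of the DG allele. The libraries held 8.65 to 15.91 M (mega) counts over 1 transcript per gene and 12.68 to 23.34 M over every transcript. WT replicates 1 to 4 held 12.43, 11.64, 14.28 and 8.65 M. DG/+ replicates 1 to 6 held 15.91, 12.66, 13.88, 12.24, 12.12 and 12.61 M. DG/DG replicates 1 to 4 held 10.31, 12.16, 12.67 and 11.55 M. Between 16898 and 17327 genes had a read in each library, and the 10 most abundant genes took 3.12% to 4.42% of the counts. Spearman's correlation of log2 CPM across genes lay between 0.976 and 0.995 for all pairs of libraries.

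The first question was whether the mutation altered the level of its own transcript. Vcp (NM_009503, chromosome 4, 42979964 to 43000507, mm10) was expressed at 97.3 ± 8.32 CPM (SD, n = 4) in WT, 99.99 ± 4.58 CPM (SD, n = 6) in DG/+ and 110.7 ± 4.59 CPM (SD, n = 4) in DG/DG. All 4 DG/DG libraries (106.6 to 115.1 CPM) lay above all WT libraries (85.3 to 103.7 CPM) and all DG/+ libraries (92.2 to 104.0 CPM). The log2 fold change of Vcp in DG/DG against WT was 0.18 (95% confidence interval 0.035 to 0.33). The exact permutation test gave p = 0.0286, the smallest that 70 splits allow, and 0.0429 adjusted over 3 comparisons, whereas the edgeR test gave an adjusted p of 0.0546 over the 3 comparisons and 0.886 over all genes. In DG/DG against DG/+ the log2 fold change was 0.15 (0.01 to 0.28), with an exact permutation p of 0.00476 (0.0143 adjusted over 3) and an edgeR adjusted p of 0.0546 over the 3 comparisons. The planned tests thus fell on either side of the threshold in both comparisons. Without WT replicate 4, the lowest library, the difference from WT was 0.13. Vcp differed between DG/+ and WT by 0.038 (-0.098 to 0.17), with an exact permutation p of 0.533. Per DG allele the estimate was 0.092 (0.019 to 0.17).

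**Figure D1:**
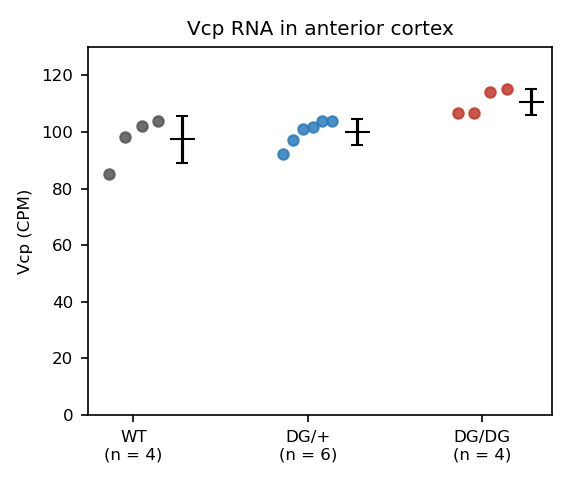
Vcp level in CPM (y axis, from 0) for each library of the 3 genotypes, points ordered by value within a genotype, with the mean and SD beside them. The 4 DG/DG libraries sit between 106.6 and 115.1 CPM, above all WT and DG/+ libraries.

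The comparison of DG/DG with WT asked what 2 mutant copies do to the cortical transcriptome. The ribosomal protein gene Rps25 was the higher gene with the smallest p and the interferon signalling gene Stat2 the lower one, and Rps7, Rpl7 and Rps2 were among the 10 first higher genes. Among gene lists, cytosolic ribosomal proteins, oxidative phosphorylation, proteasome subunits and homeostatic microglia stood higher in DG/DG with a preset correlation (adjusted p = 0.257 for the first and adjusted p = 0.8 for the others with an estimated correlation). The Vcp cofactors, the degradation pathway of the endoplasmic reticulum, and tau with its kinases were not called. No single gene passed the adjusted threshold.

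Rps25 (chromosome 9, 44407714 to 44410406) was at 36.4 ± 1.68 CPM in WT, 40.6 ± 3.05 in DG/+ and 46.2 ± 3.0 in DG/DG (SD, n = 4, 6 and 4), a log2 fold change of 0.345 against WT (SE 0.078). Stat2 (chromosome 10, 128270498 to 128292853) was at 27.2 ± 3.42 CPM in WT, 24.9 ± 1.5 in DG/+ and 19.9 ± 1.88 in DG/DG, a log2 fold change of -0.45 (SE 0.10). Both had an adjusted p of 0.886. The other higher genes by rank were Gzf1, Pgk1, Rps7, Bche, Rnf219, Serpinb9, Pdik1l, Rpl7 and Rps2, with log2 fold changes from 0.26 (Gzf1) to 0.58 (Bche). The other lower genes were Sugp1, Trim41, Tjap1, Dnm2, Zbtb7b, Srrm3, Daam2, Gtf3c2 and Mbd6, with log2 fold changes from -0.98 (Mbd6) to -0.27 (Trim41 and Dnm2). The WT and DG/DG libraries did not overlap for 17 of these 20 genes. Across all genes edgeR called 0 of 14565, with 746 at an unadjusted p under 0.05 (312 higher and 434 lower in DG/DG) where evenly spread p values give 728. DESeq2 and limma-voom also called 0, and DESeq2 found 728 at an unadjusted p under 0.05. With the libraries of the 2 genotypes regrouped, edgeR gave a median of 701 such genes, and 16 of 35 splits reached 746. The groups did not overlap for 382 genes (2.62%), and chance gives 2.86%. The 95% confidence interval of the log2 fold change reached a median of 0.28 to either side.

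Cytosolic ribosomal protein genes were higher in DG/DG as a list (camera adjusted p = 3.49e-12; adjusted p = 0.257 with an estimated correlation), with a median log2 fold change of 0.20 and 27 of 30 members higher. In this list 7 members passed when adjusted over the list alone (Rpl7, Rpl38, Rps24, Rps2, Rps14, Rpsa and Rps4x) and 0 over all genes. The mean log2 CPM of the list was 5.07 ± 0.042 in WT and 5.23 ± 0.065 in DG/DG (SD, n = 4 each). The exact permutation test of this mean gave p = 0.0286 and an adjusted p of 0.709. That p is the smallest that 70 splits allow, so a list alone at it could not pass the adjustment. All 25 oxidative phosphorylation genes were higher in DG/DG, with a median of 0.13 (adjusted p = 5.65e-08; adjusted p = 0.8 with an estimated correlation), led by Uqcrb, Uqcrc2 and Cox5b. Proteasome subunits were higher in 28 of 33 cases, with a median of 0.13 (adjusted p = 1.51e-06; adjusted p = 0.8 with an estimated correlation), led by Psmb1 (0.28), Psma7 (0.25) and Psmd6 (0.23). Homeostatic microglia genes were higher in 19 of 22 cases, with a median of 0.19 (adjusted p = 5.38e-06; adjusted p = 0.8 with an estimated correlation), among them Fcrls and Trem2. The fold changes of this comparison followed GC content (Spearman's rho -0.3 over 13412 genes) and transcript length (-0.128). These lists were still called with the length and GC offset, but other differences in RNA or library quality were not tested as their source.

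Camera called 4 further lists, all with an adjusted p = 0.828 with an estimated correlation. Immediate early genes were higher (adjusted p = 0.0165, median 0.16), with Egr2 at 0.89 and Fosl2 at 0.37. Autophagy and lysosome genes were higher (adjusted p = 0.0303, median 0.049), among them Atp6v1h and Hexa. Heat shock and disaggregation genes were higher (adjusted p = 0.0478, median 0.059), led by Hsp90aa1 (0.21) and Hspa4 (0.12). Choroid plexus and ependyma genes were lower (adjusted p = 0.0171, median -1.26), with Ttr at -4.44 and Folr1 at -3.33. The choroid plexus list rests on WT replicate 3, without which its median was -0.17 with an adjusted p of 0.713, and was not called without DG/DG replicate 1 either (0.106). With each library left out in turn, the ribosomal, oxidative phosphorylation, proteasome and microglia lists passed every time. The microglia list did not pass without DG/DG replicate 1, WT replicates 2 and 3 and DG/+ replicate 2 together (median 0.10, adjusted p = 0.0646). Immediate early genes did not pass without WT replicate 1, 2 or 3 or DG/DG replicate 1 or 2 (adjusted p 0.0949 to 0.218), autophagy and lysosome genes without WT replicate 2 or 4 or DG/DG replicate 1 or 3 (0.148 to 0.443), and heat shock genes in 9 of 14 cases (0.0508 to 0.402). Fry called 0 lists in 1 direction and 1, the ribosomal list, in either direction (adjusted p = 0.0333). Camera with an estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05.

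Tau and tau kinase genes were not called (adjusted p = 0.811, median -0.003), with Mark4 at -0.33 and Tuba1a at 0.21. The Vcp cofactors (adjusted p = 0.422, median 0.017) and the endoplasmic reticulum degradation and unfolded protein response (adjusted p = 0.183, median 0.065) were not called either, and their member Syvn1 stood at -0.28. Neurodegeneration genes gave an adjusted p of 0.483, with Abca7 at -0.38 and Trem2 at 0.40. In the interferon response list (adjusted p = 0.632), Stat2 passed when adjusted over the list alone (edgeR adjusted p = 0.0102) and 0 genes passed over all genes. Disease-associated microglia (0.249), reactive astrocytes (0.438), astrocytes (0.369), oligodendrocytes (0.265), oligodendrocyte precursors (0.401), endothelial cells (0.816), pericytes (0.249) and blood cells (0.147) had adjusted p values above the threshold. The same held for excitatory neurons (0.858), inhibitory neurons (0.816), cortical layers (0.746), striatum (0.324), olfactory bulb, hippocampus and thalamus (0.632), and synaptic genes (0.12). It also held for cholesterol synthesis (0.249), the circadian clock (0.455), DNA damage and cell cycle (0.453), and sex-linked markers (0.455).

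**Figure D2:**
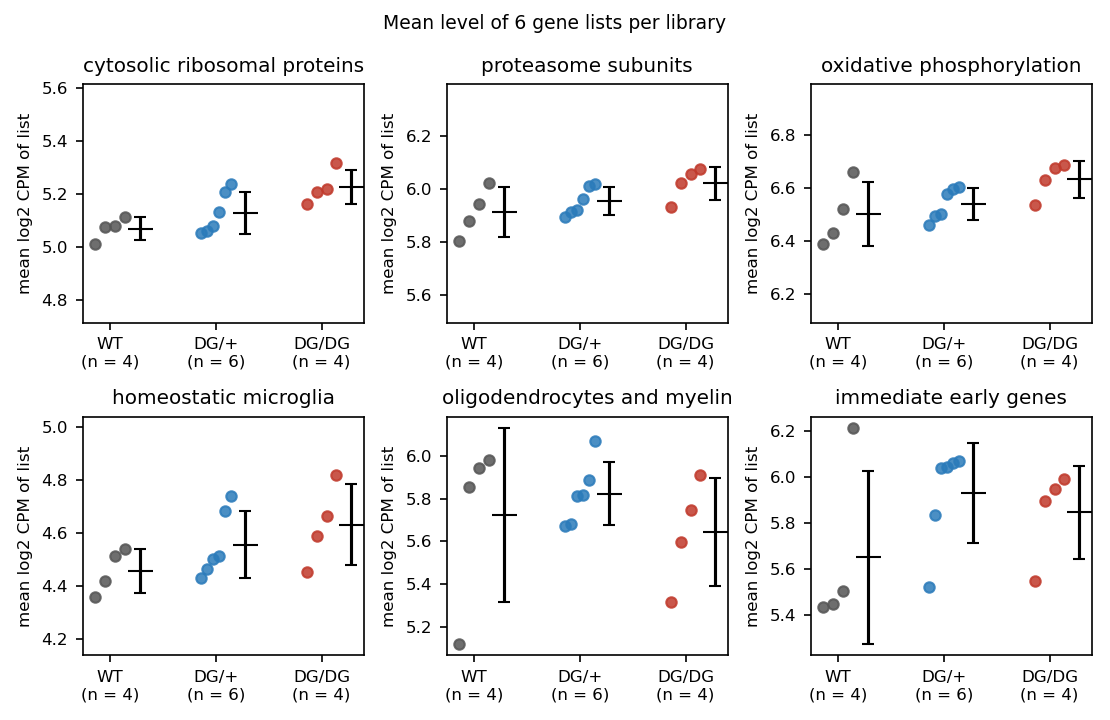
Mean log2 CPM of the members of 6 gene lists in each library (y axes span at least 0.9 and do not start at 0), points ordered by value within a genotype, with mean and SD. For cytosolic ribosomal proteins the 4 DG/DG libraries (5.16 to 5.32) lie above the 4 WT libraries (5.01 to 5.12), and the other lists overlap.

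The comparison of DG/+ with WT addressed the heterozygous state in which a dominant mutation acts. Il10ra, a cytokine receptor gene, was the higher gene with the smallest p, and Sox17, an endothelial transcription factor gene, the lower one. Immediate early genes such as Egr2, Nr4a1 and Arc and homeostatic microglia genes such as Gpr34 and Siglech stood higher in DG/+ as lists with a preset correlation (adjusted p = 0.771 with an estimated correlation for both). No single gene passed the adjusted threshold.

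Il10ra (chromosome 9, 45253837 to 45269149) was at 6.29 ± 0.48 CPM in WT and 8.82 ± 0.93 in DG/+ (SD, n = 4 and 6), a log2 fold change of 0.48 (SE 0.11). Sox17 (chromosome 1, 4490928 to 4497426) was at 4.31 ± 0.56 CPM in WT and 2.76 ± 0.45 in DG/+, a log2 fold change of -0.64 (SE 0.16). The other higher genes were Apold1, Egr2, Acvr1c, Klf11, Omp, Gabra4, Rps10, Gcnt2 and Ccl28, with log2 fold changes from 0.30 (Gabra4) to 1.58 (Omp). The other lower genes were N4bp2l1, Gkap1, Rnf215, Tmem206, Snora7a, Kiss1r, Zbtb25, Dnajc25 and Sat2, with log2 fold changes from -0.65 (Snora7a) to -0.29 (Rnf215). All adjusted p values were 1. EdgeR called 0 of 14565 genes, with 233 at an unadjusted p under 0.05 (110 higher and 123 lower) where evenly spread p values give 728. DESeq2 and limma-voom also called 0, and DESeq2 found 211 at an unadjusted p under 0.05. With the libraries of the 2 genotypes regrouped, edgeR gave a median of 585 such genes, and 91 of 100 drawn splits reached 233. The groups did not overlap for 46 genes (0.32%), and chance gives 0.95%. The 95% confidence interval of the log2 fold change reached a median of 0.25 to either side.

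Camera called 8 lists, all higher in DG/+ and each with an adjusted p = 0.771 with an estimated correlation. Immediate early genes came first (adjusted p = 3.68e-06, median 0.16, 17 of 22 higher), with Egr2 at 0.94, Nr4a1 at 0.53 and Arc at 0.48. Homeostatic microglia followed (adjusted p = 0.00223, median 0.12), with Gpr34 at 0.47 and Siglech at 0.24. The ribosomal list had an adjusted p of 0.00432 (median 0.050, Rps2 at 0.17), proteasome subunits 0.0289 (median 0.040, Psmc2 at 0.11) and oxidative phosphorylation 0.0403 (median 0.036, Uqcrb at 0.17). Across the alternative fits these medians ranged from 0.006 to 0.109, from 0.008 to 0.114 and from -0.007 to 0.102, in that order. Striatal genes had an adjusted p of 0.0205 (median 0.51, Rasd2 at 0.49), and without DG/+ replicate 4 their median was 0.12 with an adjusted p of 0.623. With each library left out in turn, only the immediate early genes passed every time, with medians from 0.12 (without WT replicate 1) to 0.36 (without WT replicate 4, the library with the highest level of this list). They did not pass without DG/DG replicate 1, WT replicates 2 and 3 and DG/+ replicate 2 together (median 0.034, adjusted p = 0.397). Homeostatic microglia did not pass without WT replicate 4 or DG/+ replicate 2 (adjusted p 0.0501 and 0.0733) nor the ribosomal list without WT replicate 2 or DG/+ replicate 2 (0.0552 to 0.2), and the other 5 lists failed in 4 to 7 of 14 cases. Cholesterol synthesis (0.0381, Lss at 0.17) and excitatory neurons (0.0472, Lmo4 at 0.22) were also called. Tau and tau kinase genes had an adjusted p of 0.265 with Cdk5r1 at 0.12, and the Vcp cofactors 0.432. In each of these lists 0 members passed adjusted over the list alone and 0 over all genes. Fry and the estimated correlation called 0 lists, with 0 at an unadjusted p under 0.05 with the estimated correlation.

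The comparison of DG/DG with DG/+ asked what the second mutant copy adds. The cystine transporter gene Slc7a11 was the higher gene with the smallest p, and the ubiquitin ligase gene Trim41 the lower one. Ribosomal, oxidative phosphorylation and proteasome genes stood higher in DG/DG, and the myelin genes Mbp and Mobp with the rest of the oligodendrocyte list stood lower, with a preset correlation (adjusted p = 0.757 for the ribosomal list and adjusted p = 0.83 for the others with an estimated correlation). No single gene passed the adjusted threshold.

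Slc7a11 (chromosome 3, 50364936 to 50499087) was at 101.7 ± 6.06 CPM in DG/+ and 135 ± 11.2 in DG/DG (SD, n = 6 and 4), a log2 fold change of 0.41 (SE 0.096). In WT it was at 105 ± 18.9 CPM. Trim41 (chromosome 11, 48806403 to 48818199) was at 43.3 ± 2.38 CPM in DG/+ and 36.5 ± 2.05 in DG/DG, a log2 fold change of -0.25 (SE 0.064). The other higher genes were Mrpl35, Umps, Pomc, Mrpl14, Gtf2b, Gh, Rps24, Zfp449 and Ysk4. Of these, Gh (6.63) and Pomc (5.97) had the largest fold changes and rest on DG/DG replicate 1, and the other 7 lay between 0.21 (Rps24) and 0.52 (Ysk4). The other lower genes were Fam50a, Stat2, Slc25a26, Txn2, Rnf207, Prrt2, Sugp1, Srpk3 and Srrm3, with log2 fold changes from -0.74 (Srpk3) to -0.24 (Srrm3). All adjusted p values were 0.972. EdgeR called 0 of 14565 genes, with 481 at an unadjusted p under 0.05 (245 higher and 236 lower) where evenly spread p values give 728. DESeq2 and limma-voom also called 0, and DESeq2 found 473 at an unadjusted p under 0.05. With the libraries of the 2 genotypes regrouped, edgeR gave a median of 400 such genes, and 45 of 100 drawn splits reached 481. The groups did not overlap for 176 genes (1.21%), and chance gives 0.95%.

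Camera called 12 lists in this comparison, 7 higher and 5 lower in DG/DG. Ribosomal protein genes were higher (adjusted p = 5.18e-08, median 0.14; adjusted p = 0.757 with an estimated correlation), with Rpl32 at 0.17. The other 11 lists each had an adjusted p = 0.83 with an estimated correlation. Oxidative phosphorylation (2.01e-05, Cox5b at 0.23), proteasome subunits (0.00101, Psma2 at 0.22 and Psmb1 at 0.20), heat shock and disaggregation (0.0144, Cct4 at 0.15), astrocytes (0.0144, Aqp4 at 0.21), homeostatic microglia (0.0251, C1qa at 0.23) and the unfolded protein response (0.0357, Pdia3 at 0.15) were higher. All 21 oligodendrocyte genes were lower (adjusted p = 0.00304, median -0.14), with Mbp at -0.47, Mobp at -0.32 and Enpp2 at -0.57. Across the alternative fits the median of this list ranged from -0.221 to -0.03. Enpp2 was high in WT replicate 3, the library with the most Ttr (786 CPM against at most 336 CPM in the other WT libraries). That library does not enter the fold change of DG/DG against DG/+. In the libraries that do, Ttr was at 525, 536 and 192 CPM in DG/+ replicates 1, 5 and 6. It was at 1.53 to 62.9 CPM in the other DG/+ libraries and at 9.05 to 18.4 CPM in DG/DG. Choroid plexus tissue as a source of the Enpp2 difference was not tested. Circadian clock genes (0.00793, Per3 at -0.33), synaptic genes (0.0144, Stx1a at -0.27 and Shank3 at -0.25), choroid plexus genes (0.0251, Ttr at -3.93) and excitatory neuron genes (0.0471, Nrgn at -0.34 and Slc17a7 at -0.19) were also lower. With each library left out in turn, the ribosomal, oxidative phosphorylation and proteasome lists passed every time. The proteasome list did not pass with the replicate number as a block (median 0.050, adjusted p = 0.0677). The fold changes of DG/DG against DG/+ followed GC content (Spearman's rho -0.246 over 13412 genes) and transcript length (-0.11), and the correlation of single libraries' log2 levels, relative to the mean of all libraries, with GC content ranged from -0.459 (DG/+ replicate 4) to 0.316 (DG/+ replicate 5). The length and GC offset took the GC trend to -0.009 but left a length trend of -0.064. With it, excitatory neurons were the only one of the lists called here that did not pass. Other differences in RNA or library quality were not tested as a source of these list calls. Without DG/DG replicate 4 neither the oligodendrocyte list (adjusted p = 0.4) nor the circadian list (0.235) passed, and the other 7 lists failed in 3 to 7 of 14 cases. In each list 0 members passed adjusted over the list alone and 0 over all genes. Fry and the estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05 with the estimated correlation.

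An effect of gene dose was sought with the number of DG alleles. Rps25 (0.17 per allele), Gzf1 (0.13), Pgk1 (0.15) and Rps7 (0.19) were among the genes that were higher with each allele, and Stat2 (-0.22), Sugp1 (-0.23) and Dnm2 (-0.13) among those that were lower. The remaining higher genes were Bche, Rnf219, Serpinb9, Rpl7, and Gh and Prl, which rest on DG/DG replicate 1, and the remaining lower genes were Tjap1, Egf, Sap25, Daam2, Lrrc29, Trim41 and Mbd6. All had an adjusted p of 0.845. EdgeR, DESeq2 and limma-voom called 0 genes. At an unadjusted p under 0.05 were 823 genes with edgeR (352 higher and 471 lower) and 808 with DESeq2, where evenly spread p values give 728. With the libraries regrouped, edgeR gave a median of 639 such genes, and 39 of 100 drawn groupings reached 823.

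Whether both mutant genotypes differed from WT in the same way was examined across genes, which are not independent replicates. Among genes with an unadjusted p under 0.05, 41 were higher in both DG/+ and DG/DG and 23 were lower in both, where independent lists would share 2.4 and 3.7. Pearson's r of the log2 fold changes over 14565 genes was 0.50 and Spearman's rho 0.52. Both fold changes use the same WT libraries, and counts simulated without any difference gave a mean r of 0.55 (0.52 to 0.60). Each gene was drawn independently there, which makes that range too narrow for real libraries. With the genotype labels of the real libraries shuffled, r ranged from 0.19 to 0.78 (median 0.54). In 62% of 100 shuffles it was at least as high as observed. With the real labels and separate WT libraries for each genotype, the mean r was -0.19. A response shared by both genotypes was not detectable beyond the effect of the shared WT libraries.

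Transcripts of other brain regions and tissues appeared in single libraries. The pituitary hormone genes Gh and Prl were at 1048 and 2735 CPM in DG/DG replicate 1 and at 17.9 and 72.6 CPM in DG/DG replicate 2. Gh did not exceed 7.32 CPM in any WT or DG/+ library. The hypothalamic peptide gene Pmch was at 40.4 CPM in WT replicate 1 and 53.1 CPM in DG/DG replicate 3, and at most 0.64 CPM in each other library. Hcrt was at 9.63 and 7.72 CPM in the same libraries. The choroid plexus gene Ttr was at 1172 CPM in WT replicate 3, at 525 and 536 CPM in DG/+ replicates 1 and 5, and between 9.05 and 18.4 CPM in DG/DG. The cerebellar gene Fat2 was at 40.8 CPM in WT replicate 2 and 41.6 CPM in DG/+ replicate 2. The cholinergic gene Chat was at 10.34, 9.25 and 13.5 CPM in WT replicate 1, DG/+ replicate 4 and DG/DG replicate 3, and at most 3.04 CPM in each other library. Lhx8, a transcription factor gene of basal forebrain neurons, was at 4.74, 3.22 and 5.62 CPM in the same 3 libraries and at most 0.98 CPM elsewhere. Reads of the Y-linked gene Ddx3y marked 2 of 4 WT, 2 of 6 DG/+ and 1 of 4 DG/DG libraries, so the genotypes held different shares of male mice.

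**Figure D3:**
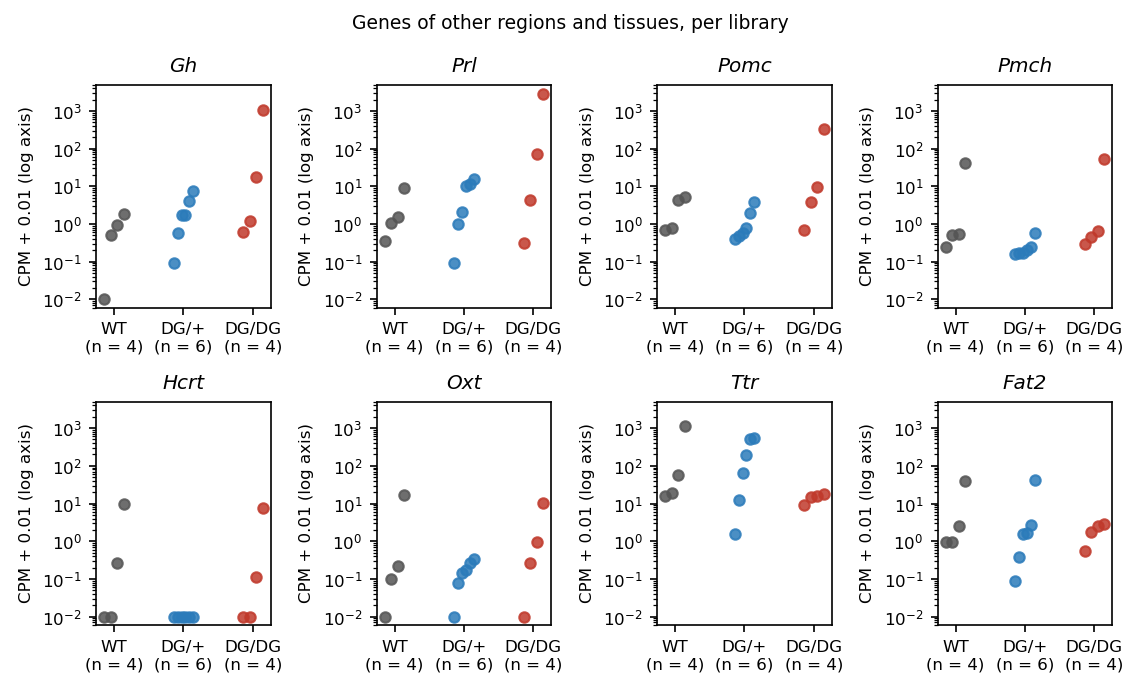
Level of 8 genes of pituitary, hypothalamus, choroid plexus and cerebellum in each library (CPM + 0.01, log axis), points ordered by value within a genotype. Gh and Prl reach 1048 and 2735 CPM in 1 DG/DG library, and Pmch exceeds 40 CPM in 1 WT and 1 DG/DG library.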

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

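The tests of the hormone genes, of the ribosomal list and of Vcp were chosen after the result was seen, except the genes around Vcp, the Xist covariate as an alternative fit, and the splits of the samples counted for gene and list calls. The ribosomal list was also singled out from 31 lists after its value was seen.

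In the authors' deposited table, Gh had a false discovery rate of 0.0364 in DG/DG against WT, with a log2 fold change of 8.15. Pmch (0.00382, log2 fold change -5.00) and Hcrt (0.0352, log2 fold change -4.90) passed in DG/+ against WT. A gap test within each genotype also set DG/DG replicate 1 apart for Gh (gap 0.984 of the range, 1049 CPM against at most 17.9) and Pomc (0.973, 322 CPM against at most 9.44).

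Of 12 pituitary markers with at least 10 reads, 91.7% had their highest level in DG/DG replicate 1, so pituitary tissue in that library is a candidate source of the Gh, Prl and Pomc reads. An effect of genotype predicts high Gh in the other 3 DG/DG libraries, and their median was 1.22 CPM, below the 7.32 CPM of DG/+ replicate 1. This argues against genotype as the source of the Gh difference.

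Hypothalamic tissue was tested in the same way for Pmch and Hcrt. In the library with the most Pmch, DG/DG replicate 3, the other 12 hypothalamic markers stood at a median of 12.6 times the other libraries, above the bound of 10 set for it. The deposited difference is between WT and DG/+, however, so WT replicate 1 was tested after the first values were seen. Here the level of the other libraries was set to at least 3 counts, a floor that the first test did not have. With that floor the median was 9.7 times, just under the same bound, so the ratios are not directly comparable. Of these 12 markers, 11 had WT replicate 1 among their 2 highest libraries. Hypothalamic tissue is therefore a candidate source of Pmch in WT replicate 1, although the ratio with the floor left it open. Genotype was tested on Pmch alone, by tests chosen after the values were seen. The other 3 WT libraries held 15 Pmch reads together (upper 95% Poisson limit 24.7), where the mean DG/+ level and the deposited fold change would give 269. Their median (0.49 CPM) was below the highest DG/+ library (0.56 CPM), and 2 DG/+ libraries reached at least the level of the lowest WT library. This argues against genotype as the source of the deposited Pmch difference, while a small difference among the other libraries would escape so few reads.

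Cytosolic ribosomal protein genes were higher in DG/DG than in WT, with a median log2 fold change of 0.20. Fold changes followed GC content (Spearman's rho -0.30) and transcript length (-0.128) across 13412 genes. An offset for length and GC removed the GC trend (-0.002) but left most of the length trend (-0.087), and with it the list's median stayed at 0.15. The 100 other genes nearest to each member in length had a median of 0.046 (SE over genes 0.010). Those nearest in length and GC content had a median of 0.066 (SE over genes 0.011). An SE over genes treats genes as independent and does not measure the spread between mice. The offset and these medians argue against length and GC as the whole cause, while a part of the rise was shared by genes of the same length. The list's median was 0.13 without DG/DG replicate 1, WT replicates 2 and 3 and DG/+ replicate 2 (adjusted p = 5.92e-05), and 0.21 with the Xist level as a covariate. These values argue against other tissue in those 4 libraries and the share of female mice as the whole cause, while tissue in the libraries that stayed in was left open. Of the 35 splits of the 8 libraries, 1, the real one, gave the list as small a camera p (12.95 as minus log10, highest other 7.4), but the list was chosen as the most extreme of 31. In 4 of the 35 splits any list had as small a p (highest other 20.45), so chance could not be excluded. Reads shared with ribosomal pseudogenes and differences in RNA quality were not tested, and a genotype effect may be present but stays a hypothesis, as the list had an adjusted p = 0.257 with an estimated correlation.

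Vcp was higher in all 4 DG/DG libraries than in any other library. With the offset, which removed the GC trend but not the length trend, the log2 fold change stayed at 0.187. The 100 genes nearest to Vcp in length had a median of -0.053 (SE over genes 0.023). Those nearest in length and GC content had a median of 0.001 (SE over genes 0.021). Leaving out the same 4 libraries gave 0.228, but WT then rested on replicates 1 and 4. Replicate 4 had the lowest Vcp of all libraries (85.3 CPM), and without it alone the difference was 0.13. The values of the offset and the matched genes argue against length and GC as the whole cause. The fit without the 4 libraries argues against other tissue in them only as far as WT replicate 4 can be relied on. The other 24 tested genes within 1 Mb of Vcp had a median of -0.134 (SE over genes 0.037), so the genes around the locus were not raised with it. Of these, Pigo, B230312A22Rik and Npr2 were lower and Creb3 higher at an unadjusted p under 0.05, 4 genes where chance gives 1.2, and with the length and GC offset the median was -0.055 and 2 genes were under 0.05. The 30 tested cofactors without Vcp had a median of 0.012 (SE over genes 0.023), so a joint rise of the cofactors is argued against. Genotype may act on the Vcp transcript, which rests on 4 DG/DG mice and stays a hypothesis.

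Chance could not be excluded for the counts of lists. As many as the 8 lists of DG/DG against WT were called in 20 of 35 splits (highest other 15), as many as the 8 of DG/+ against WT in 60 of 100 drawn splits (highest other 15), and as many as the 12 of DG/DG against DG/+ in 23 of 100 (highest other 19). For genes the real counts were 0, which every split reaches, so the splits (35 of 35, and 100 of 100 in each other comparison and with the number of alleles) say nothing about chance. The highest counts of the other splits were 185, 2, 1 and 22 genes. The split with 185 genes set WT replicates 2 and 4 with DG/DG replicates 1 and 2 against the rest, which points to a structure of the samples apart from genotype. The hypothalamic marker Gpr101 was at most 7.03 CPM in the first set and at least 24.13 CPM in the rest. Avp, Trh, Sim1, Calcr and Magel2 were also lower throughout the first set, whereas Hcrt, Oxt, Otp, Agrp, Hdc and Irs4 did not separate the sets. Tissue makeup as the source of this split was not tested.

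Within genotypes, 28 of 393 tests of a sample's gap to its group passed Dixon's 95% critical value, where about 1 in 20, or 19.6, is given by chance. The tests covered 131 genes and lists, many of them correlated. Among lists, DG/+ replicate 4 stood high for neurodegeneration genes (gap 0.657) and low for astrocytes (0.78) and synaptic genes (0.765). WT replicate 3 stood low for oligodendrocytes (0.852) and high for choroid plexus (0.894). WT replicate 4 stood high for immediate early genes (0.915), DG/+ replicate 3 for heat shock (0.754) and DG/+ replicate 6 for oligodendrocyte precursors (0.668). WT replicate 3 was also high for the choroid plexus genes Ttr (0.965) and Folr1 (0.952) and for Enpp2 (0.874), which is in the oligodendrocyte list but moved against its score. WT replicate 4 was also high for Nr4a1 (0.906).

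Single genes set further libraries apart. WT replicate 4 stood low for Hspa4 (0.892) and Pdia3 (0.894), and WT replicate 2 low for Ysk4 (0.945). DG/+ replicate 2 stood low for Sat2 (0.688), and DG/+ replicate 4 high for Psmd6 (0.634) and low for Slc17a7 (0.632). DG/DG replicate 1 stood high for Pdik1l (0.943) and Stx1a (0.99) and low for Gkap1 (0.884). DG/DG replicate 2 stood low for Txn2 (0.85), Mark4 (0.858) and Shank3 (0.852), DG/DG replicate 3 high for Cox5b (0.886), and DG/DG replicate 4 low for Dnajc25 (0.858).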

How the results depend on the processing

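The tests of every transcript, edgeR's exact test on every transcript, limma-trend on the authors' log2 values, the fit without 4 libraries (DG/DG replicate 1, WT replicates 2 and 3, DG/+ replicate 2), the length and GC offset and the permutation of list means were chosen after the data were seen, and the other alternatives were planned. Causes of the differences were not tested unless stated.

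The count of changed genes was 0 in each comparison and with the number of alleles under every alternative chosen before the data were seen. EdgeR's exact test on every transcript called 2 transcripts (Pmch and Hcrt) in DG/+ against WT and 24 in DG/DG against DG/+, among them Gh, Prl, Pomc, Tshb, Pmch, Hcrt, Ttr and Slc7a11. For 110 named genes, counted per comparison, 3294 of 3298 values kept their direction and side of the threshold, 0 reversed, and Slc7a11, Pomc, Gh and Ttr passed under that exact test. These genes were picked for small p values in the same libraries, and 0 of them passed in the main fit. Keeping direction and side thus follows largely from their choice and is no sign that their differences are real.

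Vcp in DG/DG against WT passed the threshold with DESeq2 (0.181), sample quality weights (0.208), 1 surrogate variable (0.182) and the offset (0.187). Leaving out single libraries gave 0.127 to 0.216, and it passed without WT replicate 1 or 3. In DG/DG against DG/+ it passed with DESeq2 (0.143), quality weights (0.147), 1 surrogate variable (0.152) and the offset (0.145), and single libraries gave 0.122 to 0.164. Adjusted p over 3 ranged from 0.0314 to 0.213 against WT and from 0.0370 to 0.240 against DG/+. In DG/+ against WT the small difference reversed without WT replicate 4 (-0.019), and single libraries gave -0.019 to 0.070.

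The lists called by camera depended on the set test. The estimated correlation and fry in 1 direction called 0, 0 and 0 lists in the 3 comparisons, and fry in either direction 1, 0 and 0. The permutation of list means also called 0, 0 and 0. In DG/DG against WT its smallest possible p was 0.0286, so many lists would have to reach that p for any to pass. Its result there says nothing about the camera calls. In each of the other comparisons it gave 0 lists an unadjusted p under 0.05. Without the 4 libraries 5 lists were called in DG/DG against WT and 2 in DG/+ against WT, and with the replicate block 7 in DG/DG against DG/+. Leaving out single libraries gave 5 (DG/DG replicate 1) to 13 (DG/DG replicate 2), 3 (DG/+ replicate 2) to 11, and 7 (DG/+ replicate 1) to 14 lists; without DG/+ replicate 3, 5 lists were called in DG/+ against WT. Immediate early genes reversed in DG/DG against WT without the 4 libraries (median -0.029). In that fit the median of oxidative phosphorylation in DG/+ against WT was -0.007, though its test direction stayed up (adjusted p = 0.891). With the length and GC offset the called lists stayed on their side except heat shock in DG/DG against WT (median 0.047, adjusted p = 0.0742) and excitatory neurons in DG/DG against DG/+ (median -0.088, adjusted p = 0.0560). For called lists, 131 of 160, 120 of 160 and 191 of 240 values stayed on their side. Replicate numbers did not pair the samples, with correlations of -0.215 to 0.292 between equal numbers; as a block they gave Vcp differences of 0.189, 0.080 and 0.108.

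The correlation of both genotypes' fold changes was -0.194 with WT split 2 and 2, 0.669 without WT replicate 1, 0.661 without WT replicate 3 and 0.330 without DG/DG replicate 1 (range 0.330 to 0.669 over single libraries). The pseudocount and the filter planned for normalized values were not run, as the values are counts. The 95% interval of a median gene reached 0.276 (DG/DG against WT) and 0.251 (the other comparisons) to either side, which limits smaller differences.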
